A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

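RNA from the dorsal skin of a yellow mutant of rainbow trout (Oncorhynchus mykiss) was sequenced at 1 day and at 90 days of age, with 3 libraries per age and 6 in all. The ages and replicate numbers come from the sample titles. Total RNA was extracted with Trizol from frozen tissue, per the labels' protocols. The design text of the series speaks of 3 developmental stages; the stage besides these ages was not analysed here. The labels do not say that the replicates are separate fish, so the p-values measure the spread between these samples, which may be technical.

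The deposited table held 43862 gene rows. Of these, 39849 carried an NCBI gene number, 4000 were assembled loci outside the annotation (named MSTRG) and 13 were mitochondrial genes. Bowtie2 2.2.8 and TopHat2 2.1.1 are named per the submitters' processing notes, without a role. The counting tool, the genome build and any filter are not given in the sources used here, nor is the handling of reads that match more than 1 gene or of strand. Per the file headers the authors deposited a count per gene and library, which were whole numbers, and an FPKM per gene and library. They also deposited a log2 fold change of day 90 over day 1 and an FDR, a p-value adjusted over genes, whose test is not given in the sources used here. The deposited log2 value lay within 0.01 of the log2 ratio of the ages' mean FPKM for each of the 38551 genes with FPKM above 0 at both ages. No coordinate is given because the build is not stated. Every one of the 39849 NCBI gene numbers matched the gene table of assembly USDA_OmykA_1.1, which was used for names alone. Symbols and product names were taken from the deposited table. Its product names come from best matches, 23675 of them to rainbow trout and 18079 to another species, and 2108 genes had none.

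Total counts ran from 16157312 to 18960866 per library. Genes were tested when their FPKM was at least 1 in at least 3 of the 6 libraries, which left 29436 genes holding 98.4% to 99.3% of the counts of a library, with a median count per tested gene of 202, averaged over the libraries. Counts were normalized with TMM factors and fitted with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), age being the sole term, and p-values were adjusted over all genes tested by Benjamini and Hochberg's method with a threshold of 0.05. The planned design foresaw a table of FPKM alone, to be tested by limma on log2(FPKM + 1), with edgeR taking its place should counts be present. The table held counts besides FPKM, so edgeR gives the values below and the limma fit is an alternative. Standard errors of log2 fold changes were taken as the fold change over the square root of the F statistic. Where a gene had no count in any library of an age, its fold is a lower bound against a floor of 3 counts over that age. Where it had 1 to 3 counts, the ratio of normalized counts is given with an exact 95% binomial interval. Intervals and floors cover counting error only. A floor of 3 counts is 1.58e-05% to 1.86e-05% of a library.

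On counts simulated from the means and library sizes of these samples for the 29436 genes of the comparison of day 90 with day 1, edgeR recovered 67 of 100 genes changed 2-fold and 99 of 100 genes changed 4-fold, and called 7 unchanged genes. DESeq2 recovered 75 and 99 and called 29 unchanged genes. With camera, 0 of 20 random lists and 1 of 1 planted list were called in the simulated data. There the genes varied independently of each other and few were changed, as many up as down. The simulation therefore tests neither the scaling under a wide shift between the ages nor the correlation between genes that camera assumes.

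There were 19 gene lists: melanin synthesis, pigment cell regulators, pteridine and xanthophore genes, carotenoid handling, purine synthesis and iridophores, epidermis, mucous cells, matrix and scale, muscle, erythrocyte, immune cells, cell cycle, neural tissue, lens and retina, liver and yolk, adipocyte, endothelium, thyroid axis, and stress and RNA quality. A gene matched an entry by its symbol, with or without a copy suffix, or by its product name. Genes that matched the lens and retina list by a chance likeness of symbols were kept out of it after the matches were seen. Of the 53 tested genes of the mucous list, 10 matched by both symbol and name. Lists were tested with camera of limma 3.58.1 on log2(FPKM + 1) with an inter-gene correlation of 0.01, two-sided and adjusted over the 19 lists. camera with a correlation estimated per list and fry, which tests whether the genes of a list move one way on balance, were run beside it.

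The lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, apart from what is said here to have been chosen later. The rule for named genes took the up to 4 members of each list with the smallest adjusted p and up to 2 that moved most against the list's median. It also took 12 pigment genes whatever their result, at the copy with the highest mean FPKM. From all genes it took the 10 that rose most and the 10 that fell most among those past the threshold with a mean FPKM of at least 10 at the higher age, no overlap between the ages and a name. The text gives a part of these, some are not reported here, and genes named outside the rule are said to be so. Alternatives changed the pseudocount to 0.1, the filter, the scaling, the model, the test (limma 3.58.1, DESeq2 1.42.0) or the libraries, leaving out each of the 6 in turn. limma on log2(FPKM + 1), planned for a table without counts, was added to the alternatives once counts were seen. Alternatives chosen after seeing the data were relative log expression factors, library size alone, scaling to the median ratio over the epidermis list, camera on log2 CPM from the counts, and lists of genes matched by both symbol and name. The arrayWeights alternative stopped before its convergence tolerance was reached. Robust and untrended variance fits do not enter camera and were run for genes alone.

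Same-age libraries were compared for duplicates before they were averaged. The chi-square statistic per degree of freedom was 3.17 to 33.85 between libraries of the same age, so that no pair agreed within sampling noise. For genes with several near-identical copies the deposited counts may split or share reads. In the lists, 6 pairs of copies with the same symbol had counts within 2% of each other in every library (copies of cryaa, fgb, gm1, hbb and myh4), and values of these copies are uncertain. Some genes matched more than 1 list, such as MC1R (110506598), whose product name placed it in the neural list besides.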

Results

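Skin RNA of a yellow mutant line of rainbow trout was profiled at 1 day and 90 days of age to find genes tied to the colour of the skin during development. All 6 libraries analysed here are of the yellow mutant, so that ages are compared and colours are not. Each age had 3 libraries from dorsal skin. Total counts were 17795175, 17806215 and 18395388 in the day 1 libraries and 18960866, 16816841 and 16157312 in the day 90 libraries. Between 40503 and 40640 genes had a count at day 1 and between 36743 and 36966 at day 90. The 50 most abundant genes took 12.0% to 13.4% of the counts at day 1 and 20.9% to 21.8% at day 90, and the mitochondrial genes took 2.94% to 3.36% and 3.79% to 4.38%. Levels are given below as mean FPKM ± SD (n = 3 libraries per age) and fold changes as log2 of day 90 over day 1 ± SE. A number in brackets after a symbol is the gene number of the deposited table, which tells copies of a gene apart.

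At 90 days 28 of 39 tested melanin genes were higher than at 1 day and 7 lower, 55 of 80 matrix and scale genes were higher and 16 lower, and 13 of 17 adipocyte genes were higher and 2 lower. camera called these lists up (adjusted p = 2.28e-08, 4.61e-12 and 3.83e-06), but none was called with an estimated correlation (adjusted p = 0.247, 0.265 and 0.247). With counts scaled to the epidermis list the melanin genes were 19 higher and 12 lower, the matrix and scale genes 45 and 27, and the adipocyte genes 9 and 6. tyrp1 (110500604), an enzyme of melanin synthesis, rose from 40.8 ± 3.9 to 269 ± 24 FPKM, a log2 fold change of 3.11 ± 0.15 (edgeR, adjusted p = 2e-07). Gch1 (110502330), which encodes the enzyme that opens pteridine synthesis, rose from 12.7 ± 1.9 to 114 ± 10 FPKM (log2 fold change 3.55 ± 0.14). Genes of lens and retina were lower at 90 days in all 61 tested, and most tested genes of the neural and the liver and yolk lists were lower too. The genes of the lens and retina list took 0.448 ± 0.0663% of the counts at day 1 and 0.000661 ± 2.62e-05% at day 90.

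Of 29436 genes tested, 19982 (67.9%) passed the threshold of the edgeR quasi-likelihood test, 9565 of them higher and 10417 lower at day 90. At a fold of at least 2, 4772 genes were higher and 6640 lower. At a fold of at least 10, 568 were higher and 2736 lower. For 73.3% of the tested genes the libraries of the ages did not overlap, against 10% by chance for 3 against 3. The first principal component held 94.3% of the variance, and Pearson's r across genes was 0.977 to 0.993 between libraries of one age and 0.697 to 0.757 between ages. Each gene named below as risen or fallen kept the 3 libraries of one age above the 3 of the other. The division into higher and lower genes depended on scaling: 47.9% of the calls were higher with TMM, 28.5% with library size alone and 6.9% with counts scaled to the epidermis list. With limma on log2(FPKM + 1) it was 28.9%, and 48% once FPKM were scaled by median of ratios. Other limma fits gave 25.9% with values rescaled to TPM, 28.8% with a pseudocount of 0.1 and 30.2% with arrayWeights. The median log2 fold change of the tested genes was -0.03 with TMM, -0.43 with library size alone, -0.33 with limma, -0.02 with limma and median of ratios, -0.42 with TPM and -1.48 with the epidermis scaling.

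The authors' deposited table had an FDR under 0.05 for 24450 genes, 10289 of them higher and 14159 lower. Among the genes tested here, 19164 passed in the authors' deposited table, of which 19066 also passed in edgeR and 18712 of these went in the same direction. The log2 fold changes of the authors' deposited table were lower by a median of 0.38 (difference -0.38), and Pearson's r across tested genes with a count at both ages was 0.999.

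Melanin genes rose as a list, with 28 of 39 tested genes higher, 7 lower and 4 not past the threshold, and a median log2 fold change of 1.98 (camera, adjusted p = 2.28e-08, adjusted p = 0.247 with an estimated correlation). Adjusted over the list alone, 35 passed, as over all genes. The list took 0.0673 ± 0.00314% of the counts at day 1 and 0.212 ± 0.0114% at day 90. Both copies of tyr, which encodes tyrosinase, the first enzyme of melanin synthesis, rose. tyr (100135828) went from 6.77 ± 0.79 to 24.7 ± 1.8 FPKM (log2 fold change 2.25 ± 0.12, edgeR adjusted p = 3.7e-07) and tyr (100135825) from 3.39 ± 0.062 to 24.5 ± 3 FPKM. DCT (110520164), for dopachrome tautomerase, rose from 3.45 ± 1 to 62.2 ± 4.9 FPKM (4.56 ± 0.2), and PMEL (110528226), for the fibril protein of the melanosome, from 26.6 ± 2.7 to 135 ± 10 FPKM (2.72 ± 0.13). MLANA (110523960), for a melanosome protein, rose with a log2 fold change of 3.44 ± 0.13. RAB32 (110522381), which acts in the transport of melanosome enzymes, rose from 5.1 ± 0.37 to 19.9 ± 1.9 FPKM (2.35 ± 0.11).

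Other copies of the same melanin genes fell. Of 4 tested copies of tyrp1, 1 rose and 3 fell. tyrp1 (110514819) went from 2.15 ± 0.26 FPKM to no count, at least 50-fold lower, and tyrp1 (118936625) from 5.19 ± 0.5 to 0.0233 ± 0.04, a ratio of 190 (95% interval 52 to 1600). Chosen after their values were seen, tyrp1 (110531735) fell from 13 ± 0.68 to 0.63 ± 0.29 FPKM (log2 fold change -3.99 ± 0.23), PMEL (110492024) from 27.7 ± 2 to 0.273 ± 0.17 FPKM (-6.24 ± 0.29) and DCT (110520165) from 19 ± 0.48 to 5.37 ± 1.8 FPKM (-1.45 ± 0.19). Summed over the copies, tyrp1 stood at 61.1 ± 3.7 FPKM at day 1 and 270 ± 23 at day 90, and DCT at 27.1 ± 0.78 and 86.3 ± 6.8. With counts scaled to the epidermis list, 19 of the 28 risen melanin genes stayed past the threshold as higher and the list median was 0.53, and with library size alone all 28 did. In the same day 1 libraries as these falling copies, lens and retina genes took 0.448 ± 0.0663% of the counts, against 0.000661 ± 2.62e-05% at day 90.

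**Figure D1:**
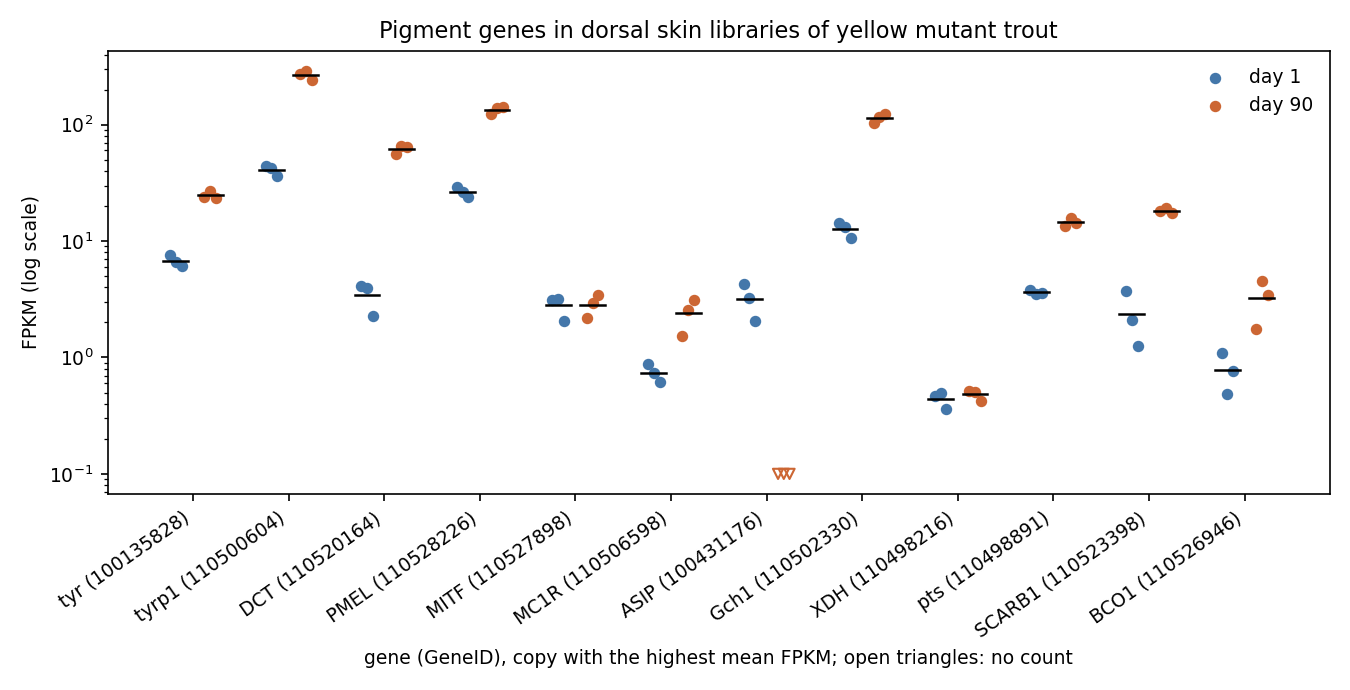
FPKM, on a log axis, of the 12 pigment genes named whatever their result, 1 point per library (3 per age), the mean of each age as a black bar and open triangles for no count; the copy with the highest mean FPKM is drawn. The 3 points of day 90 lie above the 3 of day 1 in 9 genes, as for tyrp1 (40.8 and 269 FPKM), overlap with them in MITF and XDH, and show no count in ASIP. Copies not drawn can differ: some of tyrp1, PMEL, DCT and Gch1 fell, and all ASIP copies summed to 5.53 ± 0.97 FPKM at day 1 and 1.21 ± 0.2 at day 90. The deposited product names of the drawn MC1R and MITF copies are those of other genes.

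Among genes that regulate pigment cells, 22 of 35 tested were higher, 5 lower and 8 not past the threshold (camera, adjusted p = 2.07e-05, adjusted p = 0.265 with an estimated correlation), and 27 passed adjusted over the list alone. Scaled to the epidermis list, 13 were higher and 17 lower. EDNRB (110530639), an endothelin receptor, rose from 3.2 ± 0.49 to 26.3 ± 2.3 FPKM (log2 fold change 3.42 ± 0.13). TFEC (110500235), a transcription factor of the MITF family, rose from 1.39 ± 0.26 to 9.67 ± 0.82 (3.28 ± 0.15) and kita (110516210), a receptor for kit ligand, from 1.44 ± 0.22 to 6.84 ± 0.91 (2.62 ± 0.14). PAX3 (110530949) fell from 2.7 ± 0.12 to 0.08 ± 0.01 FPKM (-4.64 ± 0.25). ASIP (100431176), which encodes agouti signaling protein, an antagonist of the melanocortin receptor, went from 3.18 ± 1.1 FPKM to no count, at least 23-fold lower (edgeR, adjusted p = 0.00021), while the other tested copy did not pass. pomcb (100136772) went from 2.24 ± 0.31 FPKM to no count, at least 53-fold lower. In the same libraries neural genes fell by a median of 4.78 on the log2 scale. Of 4 tested MITF copies 3 were higher. The most abundant, MITF (110527898), was 2.8 ± 0.64 and 2.84 ± 0.61 FPKM (0.35 ± 0.19, edgeR adjusted p = 0.12), and its deposited product name is transcription factor E3-like. MC1R (110506598) rose from 0.74 ± 0.14 to 2.4 ± 0.81 FPKM (2.07 ± 0.26), but its deposited product name is tubulin beta-3 chain-like, so that symbol and name disagree.

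Pteridine and xanthophore genes were higher in 11, lower in 4 and not past the threshold in 4 of 19 tested (camera, adjusted p = 0.00175, adjusted p = 0.247 with an estimated correlation), and 15 passed adjusted over the list alone. Scaled to the epidermis list, 6 were higher and 11 lower. Besides Gch1 (110502330), csf1r1 (110504828), a receptor of a family that xanthophores need in zebrafish, rose from 2.66 ± 0.64 to 29.7 ± 3 FPKM (log2 fold change 3.87 ± 0.17). Its deposited product name is macrophage colony-stimulating factor 1 receptor 1-like, and 37 of 45 tested immune genes were higher too. Which cells hold its transcript was not tested. SLC2A11 (110525343) rose from 2.2 ± 0.26 to 21.7 ± 0.59 (3.62 ± 0.13) and pts (110498891), for the next enzyme of pteridine synthesis, from 3.64 ± 0.15 to 14.5 ± 1.2 (2.38 ± 0.12). A second copy, Gch1 (110498968), fell from 8.16 ± 1.4 to 0.217 ± 0.16 FPKM (-4.89 ± 0.36). XDH (110498216), for xanthine dehydrogenase, stood at 0.443 ± 0.074 FPKM at day 1 and 0.483 ± 0.055 at day 90, below the filter, and was not tested.

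Of 18 carotenoid genes tested, 12 were higher, 3 lower and 3 not past the threshold (camera, adjusted p = 0.000354, adjusted p = 0.299 with an estimated correlation), and 15 passed adjusted over the list alone. Scaled to the epidermis list, 8 were higher and 8 lower. APOD (110509047), a lipid-binding apolipoprotein, rose from 5.62 ± 0.44 to 288 ± 9.1 FPKM (log2 fold change 6.06 ± 0.15). Another copy, Apod (110529118), went from 5.67 ± 2.5 FPKM to no count, at least 76-fold lower. Both ttc39b (110497341) and ttc39b (110497330) rose, by 5.07 ± 0.13 and 5.44 ± 0.17. SCARB1 (110523398), a receptor for carotenoid uptake, rose from 2.35 ± 1.2 to 18.3 ± 0.96 FPKM (3.35 ± 0.29) and BCO1 (110526946), which cleaves beta-carotene, from 0.78 ± 0.3 to 3.24 ± 1.4 (2.39 ± 0.38). rpe65a (110530459), of the visual cycle of the eye, went from 5.69 ± 0.78 to 0.0133 ± 0.023 FPKM, a ratio of 310 (95% interval 86 to 2600).

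In the purine and iridophore list, 18 of 34 tested genes were higher, 5 lower and 11 not past the threshold (camera, adjusted p = 0.00154, adjusted p = 0.247 with an estimated correlation), and 23 passed adjusted over the list alone. With library size alone 17 were higher and 13 lower, and with counts scaled to the epidermis list 6 and 18. Leaving out day 90 replicate 1 gave 17 higher and 9 lower. Pnp (MSTRG.27694), for purine nucleoside phosphorylase, rose from 9.56 ± 0.37 to 98.6 ± 6.8 FPKM (log2 fold change 3.75 ± 0.11). QNR-71 (110496588), of the GPNMB family of melanosome glycoproteins, rose from 1.48 ± 0.34 to 48 ± 2.8 (5.41 ± 0.17) and GPNMB (MSTRG.41821) from 3.13 ± 0.72 to 62.9 ± 5 (4.72 ± 0.18). PRPS1 (110489146) and impdh2 (110492316), which act in making purines, fell by 1.47 ± 0.19 and by 1.32 ± 0.15 on the log2 scale. The purine call was lost when only genes matched by both symbol and name were used (adjusted p = 0.15, with 2e-04 to 0.25 over the 18 alternatives). With counts scaled to the epidermis list, the medians of the regulator, pteridine, carotenoid and purine lists turned negative, from 0.91, 0.74, 1.22 and 0.66 to -0.54, -0.70, -0.22 and -0.78.

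Epidermis genes were higher in 58, lower in 20 and not past the threshold in 9 of 87 tested, with a median log2 fold change of 1.30 (camera, adjusted p = 6.99e-09, adjusted p = 0.247 with an estimated correlation), and 78 passed adjusted over the list alone. Krt17 (100136030) rose from 25.1 ± 4.2 to 474 ± 63 FPKM (4.62 ± 0.17) and Pkp3 (110506640), for the desmosome protein plakophilin-3, from 5.86 ± 0.63 to 36.2 ± 2.2 (3 ± 0.12). krt8 (110492482) went the other way, from 4.83 ± 0.49 to 0.0133 ± 0.023 FPKM, a ratio of 320 (95% interval 87 to 2600). Its deposited product name is intermediate filament protein ON3-like. With counts scaled to the epidermis list itself 32 were higher and 38 lower, and the median was -0.14. That scaling evens out the median ratio over this same list, so these values follow from it and do not test the epidermis rise. The list held 0.951 ± 0.00873% of the counts at day 1 and 3.64 ± 0.443% at day 90.

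Matrix and scale genes were higher in 55, lower in 16 and not past the threshold in 9 of 80 tested, with a median of 2.34 (camera, adjusted p = 4.61e-12, adjusted p = 0.265 with an estimated correlation), and 72 passed adjusted over the list alone against 71 over all genes. Postn (110503830), for periostin, rose from 43.7 ± 10 to 1370 ± 83 FPKM (5.35 ± 0.22). COL6A3 (110519979), for a chain of collagen VI, rose from 3.12 ± 0.35 to 78.3 ± 8.9 (5.03 ± 0.16) and Lox (100189621), for a collagen cross-linking enzyme, from 5.3 ± 1.1 to 111 ± 16 (4.77 ± 0.18). Another copy, Lox (110508305), fell from 12.9 ± 3.1 to 0.613 ± 0.2 FPKM (-3.97 ± 0.26). A gene named collagen alpha-1(I) chain-like (110513982) fell from 78.3 ± 14 to 0.0467 ± 0.05 FPKM (-10.32 ± 0.38). SPARC (110534308) fell from 9.51 ± 1.1 to 0.12 ± 0.085 FPKM (-5.94 ± 0.3), and its deposited product name is SPARC-like protein 1. The list's share of the counts was 1.76 ± 0.319% and 11.5 ± 0.428%.

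Immune genes were higher in 37, lower in 6 and not past the threshold in 2 of 45 tested (camera, adjusted p = 1.21e-10, adjusted p = 0.265 with an estimated correlation), and 43 passed adjusted over the list alone. With counts scaled to the epidermis list 24 were higher and 12 lower, and the median was 0.39 against 1.84. Cd74 (100136156), the invariant chain of MHC class II, rose from 2.58 ± 0.62 to 451 ± 60 FPKM (7.83 ± 0.22) and LYG2 (110517266), a lysozyme, from 1.23 ± 0.13 to 42.3 ± 3.4 (5.49 ± 0.17). The complement gene c3 (110489027) fell from 46.3 ± 15 to 0.38 ± 0.036 FPKM (-6.54 ± 0.31). Between the same ages 21 of 23 tested liver and yolk genes were lower. In the adipocyte list 13 of 17 tested genes were higher and 2 lower (camera, adjusted p = 3.83e-06, adjusted p = 0.247 with an estimated correlation), and 15 passed adjusted over the list alone. PLIN1 (110520891), which coats lipid droplets of fat cells, rose from 0.437 ± 0.11 to 70.6 ± 6.8 FPKM (7.71 ± 0.22) and Lpl (110530805), for lipoprotein lipase, from 0.133 ± 0.076 to 87.7 ± 10 (9.72 ± 0.3), while FABP4 (110505566) fell from 66.7 ± 3.4 to 1.45 ± 0.15 (-5.11 ± 0.16).

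Endothelial genes were higher in 9 and lower in 0 of 11 tested (camera, adjusted p = 0.000249, adjusted p = 0.299 with an estimated correlation), with kdr (110521673), a receptor for vascular growth factor, rising from 3.44 ± 0.56 to 9.7 ± 1 FPKM (1.9 ± 0.15). Of them 9 passed adjusted over the list alone. Of 53 mucous genes 30 were higher and 14 lower (camera, adjusted p = 0.00174, adjusted p = 0.501 with an estimated correlation), and 45 passed adjusted over the list alone against 44 over all genes. The mucous call was also lost with FPKM of at least 5 (adjusted p = 0.073) and with fry (0.65), with 0.00048 to 0.65 over the 18 alternatives. FCGBP (110519919) rose from 0.0233 ± 0.015 to 35.3 ± 17 FPKM (10.84 ± 0.53), and Muc2 (110526500) from 0.773 ± 0.04 to 23.7 ± 12 (5.3 ± 0.34). Chosen after its values were seen, another copy, FCGBP (110538705), stood at 6.6 FPKM at day 1 and 2.05 at day 90 (log2 fold change -1.31). CARMIL2 (110506560), whose deposited product name is mucin-2-like, fell from 3.97 ± 0.62 to 0.0633 ± 0.085 FPKM (-5.49 ± 0.51). With counts scaled to the epidermis list the endothelium and mucous medians were -0.50 and -0.58, against 0.94 and 0.87. Endothelial genes were then higher in 4 and lower in 6, and mucous genes in 16 and 27.

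Lens and retina genes were lower at day 90 in each of the 61 tested, 46 of which had no count there, with a median log2 fold change of -12.20 as fitted and -9.35 with these at their bound (camera, adjusted p = 6.57e-22, adjusted p = 0.265 with an estimated correlation). All 61 also passed adjusted over the list alone. CRYBB1 (110509623), a lens crystallin, fell from 208 ± 36 to 0.367 ± 0.05 FPKM (-8.41 ± 0.2), MIP (110491930), the water channel of lens fibres, from 21.5 ± 2.9 to 0.0433 ± 0.023 (-8.59 ± 0.22). CRYBA1 (110490104) went from 244 ± 32 FPKM to no count, at least 3800-fold lower. Neural genes were lower in 36 and higher in 8 of 50 tested, with a median of -4.78 (camera, adjusted p = 6.66e-06, adjusted p = 0.247 with an estimated correlation), and 46 passed adjusted over the list alone against 44 over all genes. snap25a (110522497), of the synapse, fell from 71.7 ± 8 to 0.0433 ± 0.032 FPKM (-10.28 ± 0.27). In the liver and yolk list 21 of 23 tested genes were lower and 1 was higher. Of the 23, 12 had no count at day 90, and the median was -8.22 with these at their bound (camera, adjusted p = 3.83e-06, adjusted p = 0.422 with an estimated correlation), and 22 passed adjusted over the list alone. The albumin gene alb1 (100499622) went from 422 ± 110 to 0.01 ± 0.017 FPKM, a ratio of 41000 (95% interval 7400 to 1600000), while Tf (110494108) rose from 1.79 ± 0.22 to 32 ± 1.9 FPKM (4.37 ± 0.14). The lens and retina list took 0.524%, 0.417% and 0.403% of the counts in the day 1 libraries, the same libraries in which the melanin list took 0.0694%, 0.0689% and 0.0637%.

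**Figure D2:**
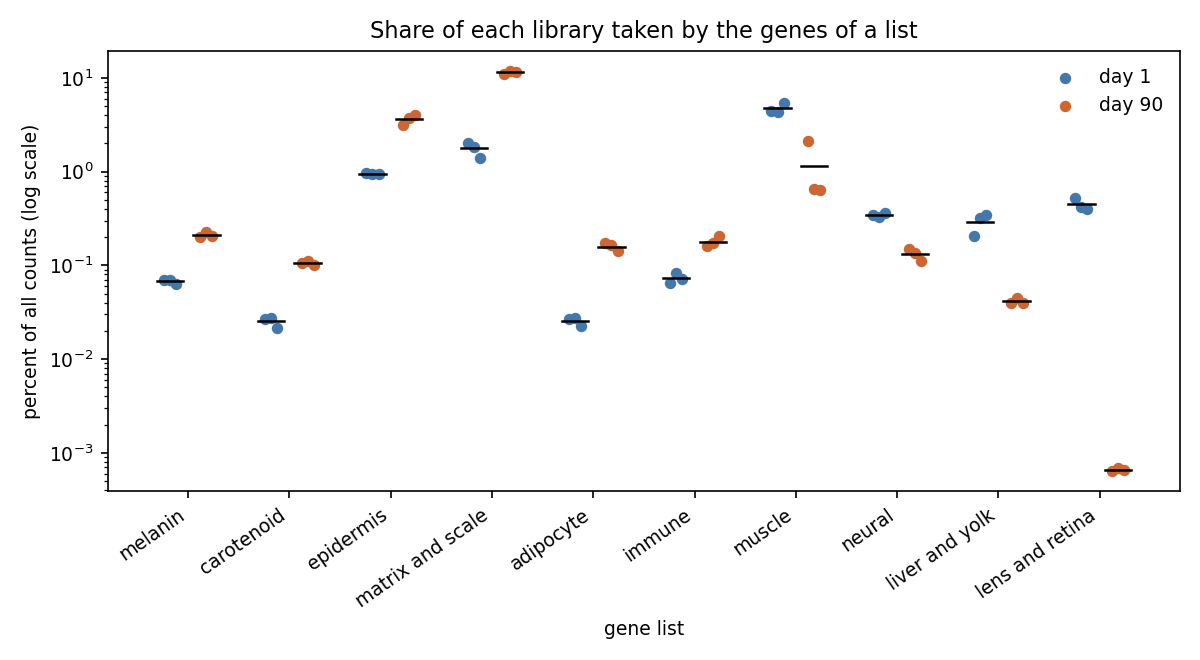
Share of all counts, in percent on a log axis, taken by the genes of 10 lists, 1 point per library (3 per age) and the mean of each age as a black bar. The lens and retina list goes from 0.448% to 0.000661%, the matrix and scale list from 1.76% to 11.5%, and 1 of the 3 day 90 libraries stands apart in the muscle list at 2.13%.

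Muscle genes were lower in 75 and higher in 29 of 125 tested, with a median of -1.67 (camera, adjusted p = 0.0338, adjusted p = 0.728 with an estimated correlation), and 105 passed adjusted over the list alone against 104 over all genes. TNNI2 (110527026), a troponin of fast muscle, fell from 557 ± 84 to 0.107 ± 0.095 FPKM (-11.81 ± 0.39). MYH4 (110495028) rose from 0.873 ± 0.015 to 15 ± 14 FPKM (4.52 ± 0.63), with counts it may share with a near-identical copy. The muscle list took 4.42%, 4.36% and 5.38% of the counts at day 1 and 2.13%, 0.647% and 0.639% at day 90, replicate 1 of day 90 standing apart from the other libraries of its age. Without it 89 were lower and 25 higher, and the median was -2.49. The call was lost without day 1 replicate 3 (adjusted p = 0.11), day 90 replicate 2 (0.087) or day 90 replicate 3 (0.12), and also with a pseudocount of 0.1 (0.081), without a filter (0.21) and with TPM (0.055). Over the 18 alternatives the adjusted p ran from 2e-05 without day 90 replicate 1 to 0.73 with an estimated correlation.

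Of the globin genes, the 7 whose deposited names are embryonic globins fell, from a summed 1470 ± 256 FPKM to 0. Of 24 other globin genes 17 rose and 5 fell, and their sum stood at 5410 ± 243 FPKM at day 1 and 10500 ± 1670 at day 90. hba1 (110538448) rose from 0.187 ± 0.2 to 627 ± 130 FPKM, and hba1 (110486355), an embryonic alpha globin, went from 896 ± 170 FPKM to no count, at least 7200-fold lower. The erythrocyte list had 18 of 36 tested genes higher and 13 lower, and 31 passed adjusted over the list alone. Its median was 0.47 and its mean -0.70, and the median was 0.07 with library size alone and -0.96 with counts scaled to the epidermis list (11 higher and 21 lower). camera called it up (adjusted p = 0.0338, adjusted p = 0.501 with an estimated correlation) and fry down (adjusted p = 0.00412). The camera call was lost without day 1 replicate 2 (adjusted p = 0.057), with a pseudocount of 0.1 (0.081), without a filter (0.13), with median of ratios scaling (0.35), without the 50 most abundant genes (0.095), with log2 CPM (0.45) and with genes matched by both symbol and name (0.75). Over the 18 alternatives the adjusted p ran from 0.0019 to 0.75.

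The cell cycle, thyroid and stress lists did not pass (camera, adjusted p = 0.174, 0.346 and 0.876, and 0.564, 0.698 and 0.942 with an estimated correlation). The cell cycle list passed as up with median of ratios scaling (adjusted p = 0.015) and with log2 CPM from the counts (0.018), with 0.015 to 0.56 over the 18 alternatives, and fry called the thyroid and stress lists down (0.0022 and 0.005). Of 38 cell cycle genes 20 were higher and 4 lower, and 23 passed adjusted over the list alone against 24 over all genes. With library size alone 8 were higher and 13 lower, and with counts scaled to the epidermis list 0 were higher and 37 lower. cdk1 (100136692), the kinase that starts mitosis, rose from 54.9 ± 1.7 to 96.1 ± 11 FPKM (1.19 ± 0.11), which turned to -0.26 with counts scaled to the epidermis list. Of 10 thyroid genes 6 were lower and 2 higher, and 8 passed adjusted over the list alone. With counts scaled to the epidermis list 10 thyroid genes were lower and 0 higher, and the median was -2.4 against -0.95. Of 33 stress and RNA quality genes 9 were higher and 10 lower, and 19 passed adjusted over the list alone. With library size alone 7 were higher and 15 lower, and with counts scaled to the epidermis list 3 and 26. The median of that list was -0.18, and -1.64 with the epidermis scaling, while the direction of camera was up. The early response gene junb (110486520) rose from 6.16 ± 0.74 to 19.6 ± 1.9 FPKM (2.05 ± 0.11), and hsp70 (110492689) fell from 17.5 ± 2.2 to 0.61 ± 0.36 (-4.42 ± 0.32).

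Among the genes that rose most, one annotated as circumsporozoite protein-like (110533145), a best-match name, went from no count to 885 ± 230 FPKM, at least 14000-fold higher. CYTL1 (110534907), for a cytokine-like protein, went from no count to 34 ± 15 FPKM, at least 350-fold higher. Among the genes that fell most, SLC1A2 (110522323), a glutamate transporter of the brain, went from 53.7 ± 3.3 FPKM to no count, at least 4600-fold lower, and a gene for apolipoprotein A-II (110537948) from 210 ± 72 FPKM to no count, at least 2600-fold lower. In total 706 called genes had no count at day 90 and 22 had none at day 1.

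Of the 19 lists, camera called 12 up and 4 down with the preset correlation and 0 with an estimated one, where 2 passed at an unadjusted p under 0.05, and fry called 17. At an unadjusted p under 0.05 the edgeR test gave 20789 genes. Splits of the 6 libraries that mix the ages called 11 to 15 lists, so that the number of lists called does not set the ages apart by itself. Each mixed split still keeps part of the age difference, since its groups hold 2 libraries of an age and 1 of the other. It is therefore no baseline without an age difference.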

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

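The alternatives chosen after seeing the data were relative log expression factors, library size alone, the scaling to the epidermis list, camera on log2 CPM, and genes matched by both symbol and name. limma on log2(FPKM + 1) was planned for a table without counts. Over 21 settings the number of genes called ran from 9742 (FPKM of at least 5, fewer genes tested) to 26457 (epidermis scaling), against 19982, and from 17925 to 19892 without 1 of the 6 libraries. Of the comparisons for single named genes, 2648 kept direction and side of the threshold, 6 lost the threshold and 10 changed direction. Of the counts of genes and lists, 4 were over 1.5 times higher and 17 over 1.5 times lower. For single lists 297 kept both, 3 came past the threshold, 32 lost it and 9 changed direction. Apart from the estimated correlation and fry, the highest adjusted p over the alternatives was 2.5e-05 for melanin, 0.00084 for pigment regulators, 0.012 for pteridine, 0.0038 for carotenoid and 0.15 for purine genes.

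The number of genes higher at day 90 was 5989 with a pseudocount of 0.1, 4706 with FPKM of at least 5, 5407 with TPM, 6084 with limma on log2(FPKM + 1), 5941 with library size alone and 1835 with the epidermis scaling. At least 2-fold higher, the numbers were 3032 with a pseudocount of 0.1, 2197 with FPKM of at least 5, 2407 with TPM, 2197 with arrayWeights, 2226 with limma, 3114 with library size alone and 1114 with the epidermis scaling. Genes lower at day 90 were 5036 with FPKM of at least 5, 16983 with arrayWeights and 24622 with the epidermis scaling, and at least 2-fold lower 10612 without a filter, 2499 with FPKM of at least 5 and 20223 with the epidermis scaling. The filter sets how many genes are tested, and scaling by TPM, library size or the epidermis list moves all genes of a library by 1 factor. With only the scaling of limma changed, to median of ratios, 9596 genes were higher in place of 6084. The fits with a pseudocount of 0.1 and with arrayWeights were also limma on FPKM without further scaling. Of their calls 28.8% and 30.2% were higher, against 28.9% with limma on log2(FPKM + 1). With a pseudocount of 0.1 and arrayWeights the median of ratios scaling was not run, and the cause was not tested. DESeq2 called 19451 genes.

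With an estimated correlation camera called 0 lists, with adjusted p of 0.25 for melanin, 0.27 for pigment regulators, 0.25 for pteridine, 0.3 for carotenoid and 0.25 for purine genes. With genes matched by both symbol and name the purine list had 0.15 and the thyroid list, whose direction turned, 0.9. fry turned the direction of the cell cycle list (0.059), the erythrocyte list (0.0041) and the stress list (0.005). The stress list also turned, never past the threshold, without a filter (0.93), with median of ratios scaling (0.93), with log2 CPM (0.98) and without day 1 replicate 2 or day 90 replicate 2 (0.72 to 1 over the libraries left out). For these lists the cause was not tested.

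MITF (110527898), not past the threshold with TMM, changed sign with TPM (-0.03), arrayWeights (-0.04), library size alone (-0.04) and the epidermis scaling (-1.1). That scaling also turned TYMS (-0.63), aurkb (-0.62), birc5.2-b (-0.71), cdk1 (-0.26), thrb (100135978, -0.67) and thrb (110488157, -0.38), by lowering every log2 fold change. Depth limits the folds of the 706 called genes without a count at day 90 to lower bounds.

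With the replicate number as a block, edgeR called 18555 genes (8764 higher, 9791 lower) and camera 16 lists. The deviations of same-numbered libraries from their age's mean correlated at -0.09, 0 and -0.12 across genes, and no number correlated best with itself, so that the labels' numbers are taken as names and not as a pairing. Robust and untrended variance fits were not run for the lists, since camera does not use them.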

Other observations

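Tests chosen after results were seen are those of the pathways, of a single mixed library, of the share of skin RNA, of the scaling and of reads shared between copies. Pathways of the deposited annotation showed further groups of genes (293 tested with camera, 10 to 300 genes each, 62 up and 19 down, and 0 with an estimated correlation, where each adjusted p was 0.998 and 5 passed unadjusted). Genes of the intestinal immune network for IgA production were higher in 30 and lower in 1 of 36 (median log2 fold change 1.67, adjusted p = 6.76e-09, median 0.23 with counts scaled to the epidermis list). Lysosome genes were higher in 150 and lower in 35 of 239 (median 0.69, adjusted p = 1.48e-06), a median that turned to -0.75 with the epidermis scaling. Genes of ribosomal proteins were higher in 154 and lower in 11 of 243 (median 0.49, adjusted p = 3.92e-05), while genes of ribosome biogenesis were higher in 7 and lower in 57 of 122 (median -0.31, adjusted p = 0.000747). The ribosome median was 0.09 with library size alone and -0.95 with the epidermis scaling, and the ribosome biogenesis median was below 0 under both (-0.71 and -1.74). Phototransduction genes, which carry the light response of photoreceptors, were lower in 26 and higher in 4 of 34 (median -1.18, adjusted p = 0.0018). Melanogenesis (79 higher and 78 lower of 218, adjusted p = 0.667) and purine metabolism (75 and 59 of 199, 0.322) did not pass. Tyrosine metabolism (25 and 11 of 47, 0.00587) and folate biosynthesis (22 and 12 of 40, 0.0104) passed as up, with medians of -0.99 and -0.81 under the epidermis scaling.

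Rainbow trout kept many gene pairs from an ancient duplication of the salmonid genome, and copies under 1 symbol were compared. Of 2564 pairs with both genes called, 2294 (89.5%) went in the same direction, against a mean of 50% and a highest value of 53.9% in 10000 permutations (p = 1e-04, the smallest they can give). Symbols come from best matches and copies can share reads, which may add to this value. In 75 of the 270 opposite pairs both copies moved at least 2-fold. Chosen after their values were seen, Pdgfrl (110504712) went from 26.9 to 224 FPKM and Pdgfrl (110489195) from 9.54 to 0.26, and fabp2 (110534299), for an intestinal fatty acid-binding protein, from 7.53 to 104 and FABP2 (110500773) from 157 to 14.3. Both fabp2 copies are among the gut markers weighed for RNA of other organs.

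Transcripts of lens, brain and liver were abundant in the libraries labelled dorsal skin of 1-day fish. A single mixed or mislabelled library is argued against, since the lens share of the lowest day 1 library was 584 times that of the highest day 90 library. Of retina and brain markers in no other list, 61.2% (93 of 152, with 12 of the 152 having an FPKM of at least 1 at day 90) were at least 10 times higher at day 1, or 69.9% of the 133 with counts enough to show such a difference (76.2% for brain and 59.2% for retina), such as PDE6G at 26.9 and 0.103 FPKM and STMN4 at 20.5 and 0, and 0 were so at day 90. Of markers of pancreas, gut, heart and kidney 48.5% were (49 markers, while 17 of this list had an FPKM of at least 1 at day 90), or 58.8% of the 80 with counts enough (77.8% for pancreas, 36.8% for gut, 56% for heart and 66.7% for kidney), such as MYL7 at 33.8 and 0.0233 FPKM and ins at 13.6 and 0, and 3 were the other way. Among all 29436 tested genes, which passed another filter than these markers, 2736 were called at least 10-fold lower at day 90. For each list as a whole both shares lie between the bounds of 25% and 75% set beforehand. Of the 6 organs 2 pass the upper bound among genes with counts enough. By these bounds alone, RNA of other organs in the day 1 samples and a change of skin with age cannot be told apart. Such RNA may come from how small fish are dissected. All 61 tested lens and retina genes were lower at day 90, 46 of them without a count there. Of 23 tested liver and yolk genes 21 were lower and 1 was higher. A change of skin alone would need skin at day 1 to express these lens, retina and liver genes together. The values argue against it as the whole cause for these lists. For the other organs both explanations stay open.

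Melanin genes were higher at day 90. The choice of TMM over library size is argued against as the whole cause. Of the 28 risen melanin genes 100% stayed past the threshold with library size alone. That change of scaling is mild, moving the list median from 1.98 to 1.59. With the epidermis scaling 19 of the 28 stayed and the median was 0.53, so that a stronger rescaling is not argued against for the others. If day 1 libraries held less skin RNA, melanin and epidermis genes would rise alike: their medians differed by 0.67 (two-sided permutation p = 0.122, 0.284 adjusted over 7 lists, 100000 permutations), and of the other 6 lists none passed when adjusted, with matrix and scale 1.03 above epidermis (0.0079, adjusted 0.0553) and purine 0.65 below (0.117, adjusted 0.284), so that this and a rise within skin cannot be told apart, the libraries of an age sharing their makeup. The permutations shuffled genes between the lists as if independent, so their p-values measure spread between genes and not between libraries. Copies of a gene often moved together, which the permutations did not take into account. An earlier form of this test, the share of melanin genes kept with the epidermis scaling (67.9%), was set aside because epidermis genes gave a like share (55.2%). Age, which the design names, stays open and untested.

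Copies of tyrp1, PMEL, DCT and Gch1 moved in opposite directions. Reads shared between these copies in a fixed proportion would keep their ratio. The copies were chosen as called in opposite directions, which already means that their ratio changed, so that this test cannot weigh shared reads. It gives the size of the shift alone. The counts of falling over rising copies were at least 35.1 times higher at day 1 in each of the 4 families (at least 23.8 times between the closest libraries of the ages), while the choice of copies asks only for more than 1. Other ways of sharing reads were not tested. Copies used in the pigment epithelium of the eye are a candidate source: 52.2% of its markers (12 of 23, 2 of the 23 at an FPKM of 1 or more at day 90) were at least 10 times higher at day 1, or 70.6% of the 17 with counts enough to show it, such as OTX2 (110529854) at 15 and 0 FPKM and RLBP1 (110521248) at 9.13 and 0.01. Transcripts of these markers were themselves present at day 1, where 11 of the 23 had an FPKM of at least 1 (median 0.913 at day 1 and 0.0167 at day 90). Both shares lie between the bounds of 25% and 75%. As the source of the falling copies, eye RNA at day 1 and a change of copy within skin cannot be told apart.

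The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 19982 genes and the highest other 0, and the real split called 16 lists and the highest other 15. In each case 1 split, the real one, reached the real value. Every other split mixes the ages, which keeps part of the age difference and puts the rest into the spread within groups. Neither count of the other splits is therefore a baseline without an age difference.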
